A study of Medicago truncatula with 6 samples.

How the data were processed

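Nuclei were isolated from roots of Medicago truncatula, a model legume, of the reference line A17. The seedlings were 6 days old and had been given water (mock) or Ensifer meliloti, the nitrogen-fixing bacterium that nodulates this plant, 48 hours earlier. Per the labels, nuclei were purified by sorting and made into 3' single-nucleus RNA libraries with the 10x Genomics v2 chemistry. The labels describe 6 libraries, 3 in each of 2 groups. They do not say whether libraries of a group came from separate plants.

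The values analysed were the mean UMI signal of each gene in each of 25 clusters of nuclei, as deposited by the authors. A UMI is a barcode that counts an RNA molecule once. Per the submitters' processing notes, Cell Ranger 6.1.1 and Seurat were used. The genome build, the annotation, the filters on nuclei, the clustering settings and the treatment of doublets are not given in the sources used here. The table holds 52709 genes, and each deposited column of signal sums to 10000, so that a value is a share of a cluster's signal in parts per 10000. The columns pool all libraries and both groups. Inoculated and mock roots could therefore not be compared, and the planned folds between groups and the planned list medians between groups were not computed. The number of nuclei and of UMIs behind each column is unknown. No SD, interval or p-value could be given, and differences between clusters have no replicate check. The clusters had been defined by the authors on the same nuclei, so genes that mark a cluster describe it and are not independent evidence.

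Of the gene rows, 3688 carried a symbol in the table itself and 49021 carried only an identifier. The supplied reference gene table shared no identifiers with these rows and was not used. The planned lists by product name, 24 in number, could not be matched and gave no result. Members of the 4 symbiosis lists had been written down before the data were examined, as older identifiers with symbols. They were matched by symbol instead, which found 33 of 34 genes. PUB1 was left out because 2 rows carry that symbol. A further 42 lists were assembled from the symbols in the table after its row names had been seen, and before their values per cluster were computed. The name of 1 of them, the Legin, legumin and LEA list, was reworded afterwards with its members unchanged. Cell classes had been planned from product names: 1 of 9 reached the 3 detected markers needed for a name. That class was pericycle, matched by 7 PHO1 symbols whose highest values fell in different clusters. All clusters were therefore left unnamed and are given by the authors' numbers.

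A gene marked a cluster when its value was at least 1 per 10000 and at least 4-fold above the mean of the other 24 clusters, with a pseudocount of 0.1 per 10000 added to both. These limits were fixed before the data were examined. Folds are on that pseudocounted scale, which understates differences of low genes. For lists, the median log2 fold of all members above 0 in any cluster was set beside 10000 random lists of the same size matched on mean expression in 20 bins. The number of random lists with a median at or above the observed one is a description of these columns and not a test between conditions. Medians were computed for 45 lists in 25 clusters, 1125 in all. A list was said to stand apart when fewer than 10 random lists reached its median, a limit chosen after the medians were seen. Likeness of clusters was measured as the Pearson correlation across 10733 genes with a mean of at least 0.2 per 10000, after subtracting each gene's mean log2 value. Genes are not independent replicates.

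Genes were named by a rule fixed in advance, with changes made once the form of the table was known. Named were all members of the 4 symbiosis lists, the 3 marking genes with a symbol and the largest fold in each cluster, and up to 4 members per other list that reached 1 per 10000 with the largest fold. The parts of the rule on rises and falls between groups could not be applied, and a symbol took the place of an informative product. The text gives a selection of these genes. Genes outside the rule are said to have been chosen after their values were seen.

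The marking step was tested on simulated data with an assumed 300000 UMIs per column, since the true depth is unknown. It recovered 100 of 100 genes planted at 8-fold and 100 of 100 planted at 16-fold, and called 0 of 52509 unplanted genes, in a run on 52709 genes. Low genes were not planted, the planted folds lay well past the 4-fold limit, and all columns had the same depth and otherwise the same profile. High scores were thus nearly fixed in advance and say little about low genes or columns of unequal depth. Alternatives tried were another fold limit, value limit, reference, pseudocount, scaling and set of columns. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.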

Results

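Expression in root nuclei was described for 25 clusters, pooled over 3 mock and 3 inoculated libraries. The study's design sets roots given E. meliloti for 48 hours against mock roots, but the pooled columns hold no value for either group alone. What follows compares clusters, with 1 value per gene and cluster and no replicates. Values are parts per 10000 of a cluster's signal, and depth is unknown. Of 52709 genes, 34683 were above 0 in at least 1 cluster, 10694 were above 0 in every cluster, and 8355 reached 1 per 10000. The genes above 0 per cluster ranged from 15911 in cluster 19 to 28098 in cluster 21.

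The first question was which genes set each cluster apart. In total 3979 genes marked a cluster, 510 of them with a symbol. Of these 3979 genes, 3111 marked 1 cluster and 767 marked 2, and no gene marked more than 4. The strongest fold among the named genes was that of the class III peroxidase MtPrx55, at 64.2 per 10000 in cluster 19 and 368-fold above the mean of the others. In cluster 3, MtPrx100 reached 20.1 (132-fold) and MtEXP7, named as an expansin, a class of wall-loosening proteins, reached 5.10 (46.0-fold). MtNodGRP39, named as a nodule glycine-rich protein, stood at 154 in cluster 16, 138-fold above the others. MtMATE12 was at 11.6 in cluster 24 (104-fold). The number of marking genes ran from 11 in cluster 12 to 443 in cluster 24, with a median of 179. Clusters 10 and 12, with 13 and 11 marking genes, were also the closest pair (r = 0.75 across genes), followed by clusters 1 and 2 (r = 0.74) and clusters 21 and 23 (r = 0.68). The total number of marking genes depended on the limits: it was 2046 at a fold limit of 8, 1141 with a pseudocount of 1, and 1071 when the highest other cluster replaced the mean.

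**Figure D1:**
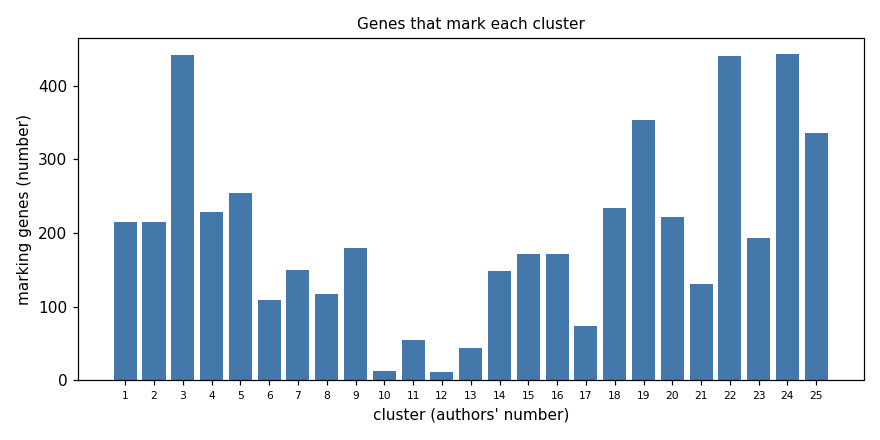
Number of genes that mark each cluster (y axis) by the authors' cluster number (x axis), 1 bar per cluster. Bars run from 11 in cluster 12 to 443 in cluster 24.

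Genes of Nod factor perception and common symbiosis signalling, the pathway that recognises rhizobial signals, had their highest values mainly in clusters 2 and 3. Of the 11 genes, 5 were highest in cluster 2 and 4 in cluster 3. MtNIN, a transcription factor required for nodulation, stood at 0.640 in cluster 2 and 0.631 in cluster 3. MtNSP1, a GRAS-family regulator of the pathway, was at 1.11 in cluster 2, 5.74-fold above the others. MtERN2, an ERF-type transcription factor, was at 1.19 in cluster 3 (8.68-fold), and the receptor kinase gene MtDMI2 was at 6.04 in cluster 3 and 4.68 in cluster 2. The Nod factor receptor genes MtNFP and MtLYK3 were highest in cluster 2, at 0.554 and 1.72, but MtLYK3 was nearly as high in cluster 13 (1.60). The exceptions were MtDMI3, the calcium- and calmodulin-dependent kinase of the pathway, highest in cluster 19 at 5.87, and MtDMI1, highest in cluster 23 at 0.525. The list's median log2 fold was 1.82 in cluster 2, reached by 0 of 10000 random lists, and 1.46 in cluster 3, reached by 1. In cluster 1 it was 0.51, reached by 4.

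Genes of rhizobial infection showed the same pair of clusters. Of 11 genes, 4 were highest in cluster 2 and 4 in cluster 3. MtCBS1 was at 6.12 in cluster 3, 41.3-fold above the others, and MtRPG, required for infection thread growth, was at 4.55 in cluster 3 and 3.05 in cluster 2. MtNPL, a pectate lyase of infection, was at 0.725 in cluster 3, and MtENOD11, an early nodulin, was at 0.481 there, with 75.6% of its summed signal in that cluster. MtLIN;MtPUB9, an E3 ubiquitin ligase gene, was at 3.40 in cluster 2 and MtFLOT4, a flotillin, at 0.919. MtLYK10 was nearly as high in cluster 19 (1.09) as in cluster 2 (1.15). The peroxidase gene MtPrx01;MtRIP1 was highest in cluster 7, at 5.71. MtFLOT2 and MtSYMREM1;MtREM2.2 did not exceed 0.0156 and 0.0727 in any cluster. The list's median log2 fold was 2.29 in cluster 2 and 1.80 in cluster 3, each reached by 0 of 10000 random lists. Several of these genes lie below 1 per 10000, where the pseudocount sets the size of the fold: with a pseudocount of 1 the medians were 0.65 in cluster 2 and 0.43 in cluster 3.

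**Figure D2:**
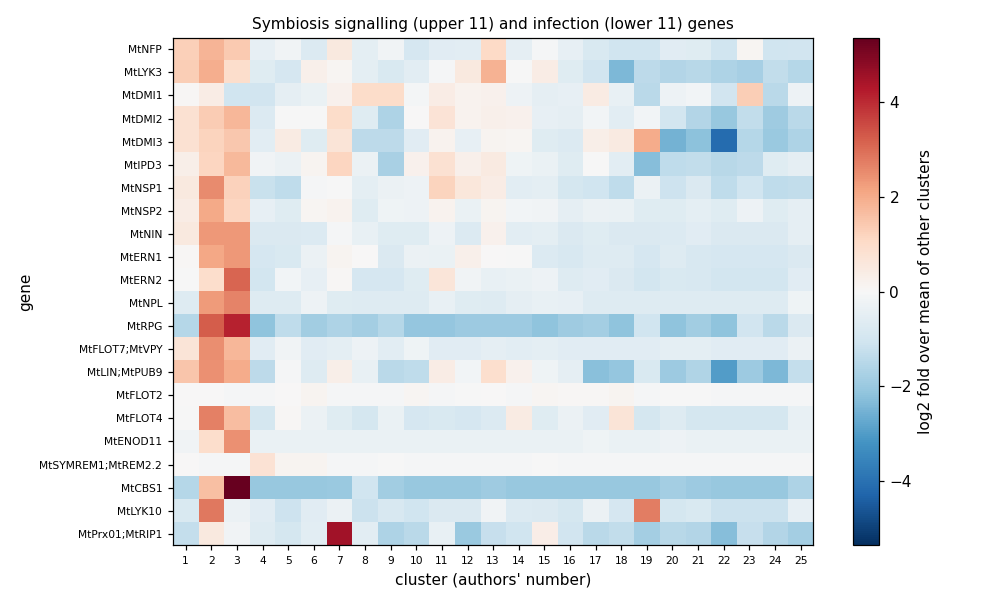
Log2 fold of 22 symbiosis genes (rows) in each of 25 clusters (columns) over the mean of the other 24, with a pseudocount of 0.1 per 10000. The upper 11 rows are signalling genes and the lower 11 infection genes; the darkest cell is MtCBS1 in cluster 3, 41.3-fold above the others.

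The 8 nodule organogenesis genes had their highest values in clusters 2, 7, 19, 20 and 25. Their median log2 fold was largest in cluster 20, at 0.60, reached by 1 of 10000 random lists. MtRRA4;MtRR4, a cytokinin response regulator, stood at 0.923 in cluster 20, and MtHMGR1 at 1.09 there and 1.04 in cluster 17. MtIPT3, of cytokinin synthesis, was at 1.15 in cluster 25. MtNF-YA1, a CCAAT-binding subunit, was at 0.180 in cluster 2 and MtENOD40 at 0.705 in cluster 19. Of the autoregulation genes, which limit nodule number, the receptor kinase gene MtSUNN was at 6.60 in cluster 25, with 96.9% of its summed signal there. The peptide genes MtCLE12 and MtCLE13 were listed at 0 in every cluster.

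Lists drawn from the table's own symbols, not fixed in advance, stood apart in clusters 2 and 3 and in others. Of 40 such lists outside the organelle models, 16 stood apart in at least 1 cluster, in 22 of 1000 medians, where 1 would do so if the lists were random. The random lists were drawn from all genes above 0, most without a symbol, and the limit was chosen after the medians were seen. That 1 is therefore no measure of what lists of related genes with symbols would give. Cell division genes were highest in cluster 9. Of 15 A- and B-type cyclins above 0, 13 were highest in cluster 9, and the list's median log2 fold there was 1.31, reached by 0 of 10000 random lists. Most of these genes are low, and the median was 3.54 with a pseudocount of 0.01 and 0.20 with a pseudocount of 1. MtCycA1-1, a mitotic cyclin by name, was at 1.30. Replication proteins had a median log2 fold of 1.46 and stem cell niche factors one of 1.09 in the same cluster, each reached by 0 of 10000 random lists. MtPLT5 was at 2.21 in cluster 9, whereas MtSCR, a GRAS factor known from endodermis patterning, was at 3.60 in cluster 19 and MtSHR2 at 1.01. Auxin synthesis genes had a median log2 fold of 1.20 in cluster 9 and 0.98 in cluster 21, each reached by 0 of 10000 random lists. Among the 5 members with a mean of at least 0.02, the median in cluster 9 was 1.37, reached by 27 random lists, so that the list no longer stood apart.

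The medians of the auxin transport and vascular lists were largest in cluster 23, where 5 of 13 auxin transport genes and 7 of 14 vascular factors had their highest value. Auxin carriers had a median log2 fold of 0.85 over 13 genes in cluster 23 (0 random lists) and 0.66 in cluster 21 (1 random list). With a pseudocount of 0.01 the median in cluster 23 was 0.95, reached by 12 random lists. MtLAX5 was at 5.21 and MtPIN6 at 2.45 in cluster 23. Vascular factors had a median of 1.61 in cluster 23 (0 random lists), and MtT5L1b was at 7.78 there. MtVND4 and VND7-like, named for vessel-related NAC factors, were highest in cluster 24, at 1.78 and 1.79. Auxin response factors had a median log2 fold of 0.41 in cluster 21 (3 random lists), and with a pseudocount of 0.01 one of 0.48, reached by 16.

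High-affinity nitrate transport genes had a median log2 fold of 3.15 in cluster 2, 2.09 in cluster 13 and 1.77 in cluster 1, over 5 genes and each reached by 0 random lists. MtNAR2.2, the partner protein of these transporters, was at 15.9 in cluster 2 and 13.7 in cluster 13. Cluster 20 carried MtNPF7.9 at 27.5, MtNPF7.8 at 25.2, MtNPF6.4 at 16.9, MtSWEET12 at 10.6 and MtSWEET3c at 10.3. MtPHO1.2, of the PHO1 phosphate exporter family, was at 59.6 in cluster 5 and 57.9 in cluster 20, while MtPHO1.4 was at 8.07 in cluster 3. The NPF, SWEET and PHO1 lists did not stand apart as wholes in any cluster. Cluster 25 held the proton pump gene MtAHA3 at 23.1 (90.8-fold) and the peptide gene MtCLE01/CLE25 at 5.76 (45.9-fold).

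Of 8 suberin and wax enzymes above 0, 5 were highest in cluster 16, and of 10 NADPH oxidases, 3 were highest in cluster 3 and 3 in cluster 19. Suberin and wax enzymes had a median log2 fold of 2.15 in cluster 16 (0 random lists) and 0.88 in cluster 15 (1 random list). MtCER3 was at 16.8 and MtKCS2 at 7.34 in cluster 16, but MtCER1-2 was at 16.1 in cluster 3. NADPH oxidases had a median log2 fold of 0.92 in cluster 3 (1 random list), with MtRbohF at 16.9 and MtRbohI at 9.48, while MtRbohJ was at 23.9 in cluster 19. Of 79 class III peroxidases above 0, 43 marked a cluster, but the list did not stand apart in any. Flavonoid and phenylpropanoid enzymes had a median log2 fold of 0.58 in cluster 14 (0 random lists), where 7 of 17 were highest, but MtF3H-2 was at 9.27 in cluster 3. Cytokinin receptors and A-type response regulators had medians of 0.82 in cluster 7 and 0.45 in cluster 20, each with 0 random lists. Ethylene receptors and ACC synthases had one of 0.42 in cluster 7, and PR proteins one of 0.24 in cluster 6, each with 0 random lists. The PR protein median was 1.01 with a pseudocount of 0.01, 0.028 with a pseudocount of 1, and 1.06 among the 14 members with a mean of at least 0.02. LysM receptors, 3 of which are also in the symbiosis lists (MtNFP, MtLYK3 and MtLYK10), had a median of 0.31 in cluster 2 (2 random lists). Among the 15 members with a mean of at least 0.02 it was 0.070, reached by 110 random lists. Lipid transfer proteins had a median log2 fold of 0.022 in cluster 6 (4 random lists), and one of 0.38 among the 38 members with a mean of at least 0.02. Apart from the organelle gene models, the other lists did not stand apart in any cluster, among them the Legin, legumin and LEA list, of which 6 of 46 genes reached 1 per 10000.

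**Figure D3:**
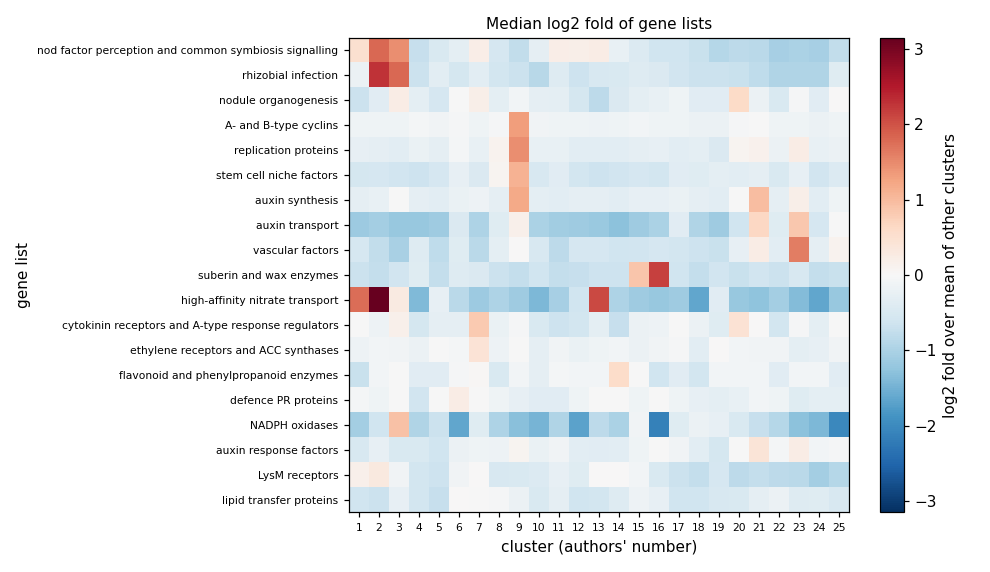
Median log2 fold over the mean of the other 24 clusters for gene lists (rows) in each of 25 clusters (columns). The upper 3 lists were fixed before the data were examined and the rest were assembled from the table's symbols; the largest median is 3.15, for high-affinity nitrate transport in cluster 2.

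Nodule gene families differed in how many members were above 0, beside 34683 of all 52709 genes. Of 11 leghemoglobin genes, which bind oxygen in nodules, 4 were above 0, and MtLb4 reached 1.09 in cluster 15. Of 688 nodule-specific cysteine-rich peptide genes, 120 were above 0 and 2 reached 1 per 10000, MtNCR674 at 3.47 in cluster 20 and MtNCR122 at 1.21 in cluster 10. Of 47 nodule glycine-rich protein genes, 26 were above 0 and 3 reached 1, among them MtNodGRP39 at 154 in cluster 16. No member of the 9 mycorrhiza genes reached 1.

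Cluster 8 differed in its organelle signal. Mitochondrial gene models made up 20.5% of its signal against a median of 0.644% over the clusters, and 70 of its 117 marking genes were mitochondrial and 9 chloroplast models. None of the 117 carried a symbol, but the organelle models were recognised by their identifiers, so only the other 38 could have done so. A single gene model, MtrunA17Chr7g0260631, was at 1007 per 10000 in cluster 8, 152.5-fold above the others. It was chosen after its value was seen. As lists, the mitochondrial models stood apart in clusters 3, 6, 8 and 9 and the chloroplast models in clusters 6, 8, 9, 13 and 16, each with 0 random lists. Sizes differed widely, and a median near 0 could stand apart where matched random lists lay lower still. The mitochondrial median log2 fold was 2.06 in cluster 8, 0.31 in cluster 9, 0.034 in cluster 6 and -0.038 in cluster 3. The chloroplast median was 1.67 in cluster 6, 0.49 in cluster 9, 0.46 in cluster 8, 0.070 in cluster 16 and 0.043 in cluster 13. In cluster 6, chloroplast models made up 1.57% of the signal and 34 of 109 marking genes.

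**Figure D4:**
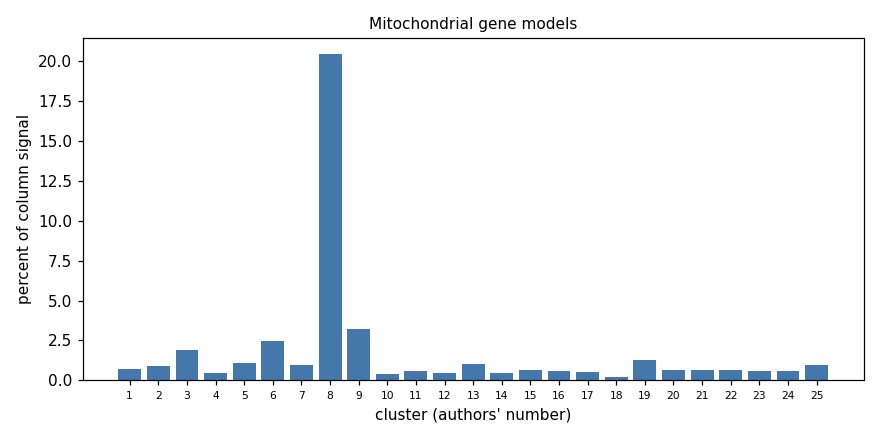
Percent of each cluster's signal in mitochondrial gene models (y axis) by the authors' cluster number (x axis), 1 bar per cluster. Cluster 8 stands at 20.5% and the next, cluster 9, at 3.20%.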

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

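All alternatives for list medians and single genes were chosen after seeing the data, as were those with another pseudocount, scaling or set of clusters for the number of marking genes. That number, 3979, was 2046 at a fold limit of 8, 1071 against the highest other cluster and 1141 with a pseudocount of 1, since each makes the limit stricter. It was 5669 at a value limit of 0.2, 4420 with a pseudocount of 0.01, 3913 without organelle models, 3888 without cluster 8 and 2854 without clusters 3, 19, 22 and 24, which had the most marking genes. The medians of the signalling and infection lists in clusters 2 and 3 and of the organogenesis list in cluster 20 stood apart under all 6 alternatives, but a pseudocount of 1 shrank them, for signalling in cluster 2 from 1.82 to 0.65. Of 21 list medians recomputed, none changed sign, but their size depended on the treatment of low genes. All 21 were more than 1.5 times smaller with a pseudocount of 1, and 10 were more than 1.5 times larger with a pseudocount of 0.01. Among members with a mean of at least 0.02, 8 were larger and 1 smaller by that factor, and 4 were larger with each column's median set to 0. With a pseudocount of 0.01, the median of auxin transport in cluster 23 went from 0.85 to 0.95 but was reached by 12 random lists, and that of auxin response factors in cluster 21 from 0.41 to 0.48, reached by 16. Among members with a mean of at least 0.02, that of auxin synthesis in cluster 9 went from 1.20 to 1.37, reached by 27, and that of LysM receptors in cluster 2 from 0.31 to 0.070, reached by 110. The cause was not tested. Of 194 genes followed in their highest cluster, 93 that were past the 4-fold limit no longer were against the highest other cluster, and 84 no longer were with a pseudocount of 1. A further 13 passed it with a pseudocount of 0.01. No paired analysis was possible because the columns pool the libraries. For the same reason the other settings listed beforehand were not run: those for folds and list medians between groups, and marking genes from inoculated columns alone. Unknown depth leaves values of 0 and low values without a limit.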

Other observations

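The tests of this part were chosen after the results they concern had been seen, except 2 whose outcome was unseen when they were written down: whether the large gene model of cluster 8 follows the mitochondrial signal, and the share of marking genes in the 6 columns with the largest lowest value. The genes named here were also chosen after their values were seen.

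Clusters 2 and 3 shared genes beyond the symbiosis lists. A search for genes that reached 0.3 per 10000, had at least 70% of their summed signal in these clusters and were more than 2-fold above every other cluster in both found 57. Its limits were set after looking at the values. No pseudocount was used, and 0.3 had to be reached in only 1 of the 2 clusters, so some genes were low in the other. MtAHA1 was at 0.690 in cluster 2 and 0.0487 in cluster 3, and 1 gene without a symbol was at 0.0106 in cluster 2. Other pairs of clusters were not searched, so whether 57 is many is not known. Of the 57, 23 carried a symbol (40.4%, against 8.11% of all 17011 genes reaching 0.3) and 6 were in the symbiosis lists. Symbols are given more often to studied genes, so this share is no measure of function. MtNFH1, a Nod factor hydrolase, was at 1.94 in cluster 3 and 1.63 in cluster 2. MtCHIT5b, a chitinase, was at 0.873 in cluster 2 and 0.336 in cluster 3. Some were far from even: MtD27, named for a strigolactone synthesis enzyme, was at 3.96 in cluster 2 and 0.346 in cluster 3, and MtPrx02 at 13.0 in cluster 3 and 0.956 in cluster 2. The other 34 carried identifiers without symbols.

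Further symbiosis genes lay in these clusters and elsewhere. Of the rows that carry the PUB1 symbol, MtPUB1; MtPUB45 was at 1.46 in cluster 2 and 0.874 in cluster 3, while MtPUB1 was highest in cluster 9, at 0.146. MtNMN1 was at 0.306 in cluster 3 and 0.131 in cluster 2. MtSYFO1, a formin gene, was at 5.02 in cluster 19, MtCRA2, a receptor kinase gene, at 4.92 in cluster 25, and MtTML2 at 1.35 in cluster 20 with 75.9% of its summed signal there. Others were spread more evenly: MtTML1 had 7.79% of its summed signal in its highest cluster, 17, and MtRDN1 18.8% in cluster 24. MtSUT1-1, a sucrose transporter gene, was at 24.3 in cluster 25.

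The likeness of clusters 2 and 3 for symbiosis genes was weighed against 2 technical explanations. Of 22 signalling and infection genes, 15 had both their highest values in clusters 2 and 3. A first explanation is that the 2 columns are alike for genes in general. Of 10000 matched random lists, 0 held as many such genes, and the most in any was 3. That cannot decide, since random genes need not be highest in cluster 2 or 3 at all. Most of the 22 had already been seen to be highest there. Cluster 2 was also the column closest to cluster 3 across genes (r = 0.37), so general likeness stays open. Sparse sampling of cluster 3, as a source of large folds, would act alike on genes of like mean expression, whether it raises or lowers them. Matched random lists would then reach such medians in that column as readily. Of 10000 such lists, 0 reached the infection median of 1.80 and 1 reached the signalling median of 1.46. With a pseudocount of 1, 0 reached either median. These counts argue against that explanation for the 2 lists as sets, but not for single genes. In the 6 columns with a larger lowest value than cluster 3, the infection list's median log2 fold over the columns other than 2 and 3 lay between -0.175 and -0.0923. This comparison with other columns does not decide, since sparse sampling also sets low genes to 0 and so lowers a median. The depth of cluster 3 is unknown. A further hypothesis is that these clusters hold cells responding to rhizobia; since mock and inoculated nuclei are pooled, it was not tested, and cells that express these genes before contact may account for the 15 as well.

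The organelle signal of cluster 8 may come from organelle RNA added to nuclei of mixed types. Without organelle models and the large gene model, 97 marking genes were left after rescaling, under the lower quartile of 119 in the other clusters, as that explanation needs. The count depended on the choice: it was 38 outside the organelle models as deposited, and 68 with organelle models removed and the large gene model kept. A remainder stays open: 86 of the 97 were highest in cluster 8, and 6 other clusters had fewer marking genes. Among the 97, 3 carried a symbol. The highest value among them was 170 per 10000 and the largest log2 fold 7.40, both after rescaling. The count of 97 alone therefore does not settle the first explanation. Nuclei of mixed types should also lie near the mean of the other clusters. Without organelle models and the large gene model, r of cluster 8 with that mean was 0.76 on log2 values of 10637 genes. It ranked 6 among 25 clusters, whose r ran from 0.48 to 0.78. That rank does not decide either, since other clusters lay nearer to their mean. A second explanation is that the large gene model collects a fixed share of mitochondrial reads. It needs the model to follow the mitochondrial sum across the other 24 columns. The model did not: r was -0.11, and 59.7% of 10638 genes followed the sum at least as closely. The test is weak where organelle signal is low, since the model's own RNA may set its value there. In cluster 9 the mitochondrial models summed to 320 per 10000, against 2046 in cluster 8. The large gene model was at most 12.2 in cluster 9, against 1007 in cluster 8. Chloroplast models summed to 157 per 10000 in cluster 6 and 69.0 in cluster 8. In cluster 6, too, the large gene model was at most 12.2. The values of clusters 6 and 9 argue against a fixed share of either organelle's reads as its source, with 1 value per cluster and no replicates. No biological explanation was tested.

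The number of marking genes per cluster could reflect counting noise in sparse columns. Raising the value limit from 1 to 5 per 10000 should then lower their share of marks, if such noise reaches the lower limit. In the 6 columns with the largest lowest value the share was 38.2% and then 39.7%. In the 4 columns with the fewest genes above 0 it was 30.1% and then 30.5%. The shares argue against noise near the limit as the source in these columns. Clusters 19, 22 and 24 are in both sets, so these are not separate lines of evidence. Cluster 3, with 442 marking genes, is in neither. The lowest value above 0 was at most 0.0204 in any column, far under both limits, so values near the floor were not tested. Noise near that floor would hardly change the marks at either limit, so the shares cannot decide. The number of nuclei per cluster stays unknown. No biological explanation was tested.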
